A study of Mus musculus with 6 samples.

How the data were processed

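Expression was measured in mouse bone marrow on Affymetrix Mouse Gene 1.0 ST arrays, single-colour arrays whose probes are spread along each transcript and summarised into transcript clusters. Per the labels, 3 arrays carried RNA from Scf-GFP+ cells and 3 carried RNA from whole bone marrow cells, from young adult mice on a C57BL/6 background. Scf-GFP+ cells are cells that switch on a green fluorescent protein placed in the gene for stem cell factor, whose symbol is Kitl. They came from mice heterozygous for this knock-in and were double-sorted, while whole marrow cells came from wild-type mice and were sorted with no second pass named, so cell population, genotype and handling changed together between the groups. Each array had 5000 cells sorted into Trizol. Their RNA was treated with DNase, amplified with the NuGEN Pico system, turned into sense-strand cDNA, fragmented and labelled with biotin, per the labels' protocols. Amplification of RNA from so few cells and the summary of probes into clusters both limit how exactly a large difference is sized, and a strong probe set can saturate.

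The authors deposited 1 table of log2 values for the 6 arrays. The submitters' processing notes name RMA, affy and limma, without versions or roles. RMA corrects background, equalises the arrays' quantiles and summarises probes by median polish, and the range and spread of the deposited values are those of such a log2 summary. The build and version of the array annotation are not given in the sources used here. The deposited log2 values were used as they stand, with no further normalization. Their medians lay between 6.564 and 6.631 on the 6 arrays. RMA values have no detection call, so a low value is not read as absence of a transcript, and no level of one gene is set against that of another.

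The table had 28940 rows. The probe annotation listed exactly 1 gene symbol for 21789 rows, several for 1621 and none for 5530. Symbols were updated through Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6, and the symbol of 91 rows whose identifier was not found there was kept as listed. No coordinates are given, because the annotation's build is not named. Rows with 1 symbol entered the tests. For 999 genes with several such rows, the row with the highest mean over all 6 arrays stood for the gene, which left 19938 genes. Families with near-identical copies, such as Akr1c19, C1s1, C4b, Chil3, Hspa1a, Kng1 and Vpreb1, are uncertain as to which copy was measured.

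Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with statmod 1.5.0, without covariates. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested together with a difference of at least 2-fold. Differences are Scf-GFP+ minus whole bone marrow on the log2 scale, with limma's moderated standard error (SE). Every adjusted p of a gene in the text comes from limma. The labels speak of independent aliquots and do not say whether these came from separate animals, so p-values measure the spread between these samples, part of which may be technical.

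Gene lists of cell types, pathways and complexes, 38 in number, were written before the data were examined, as were the design, the named-gene rule and all alternatives listed below except the term for sex. For each list the called members were counted, over all genes tested and adjusted over the list alone. These counts were equal unless the text gives both. The lists were tested with limma's camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the arrays, each adjusted over 36 lists. The other 2 lists, of reference genes and sex-linked genes, served for quality only. Of the 36 lists, 28 passed an adjusted p of 0.05 with the preset correlation and 8 with the estimated one. That estimate is imprecise with 6 arrays, and camera then also uses fewer degrees of freedom, which raises p-values by itself. Lists overlap in part. Named genes are 12 genes fixed in advance, the 15 genes per direction with the largest difference among called genes with no overlap between the groups, leaving out unnamed transcript models, small RNAs, olfactory and vomeronasal receptors and antigen receptor segments, up to 4 members per list with the largest differences, and further members needed to describe a list.

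The fit was tested on simulated data with the real arrays' means and spreads for the 19938 genes, 200 of them changed in each of 10 runs. It recovered 75.5% of genes changed by 1.50 on the log2 scale, 86.1% of those changed by 2.00 and 95.8% of those changed by 3.00, with a mean of 2.6 false calls per run. The adjusted p depends on the share of changed genes, and 3370 genes were called in the real data. The recovered shares and the 2.6 false calls therefore do not carry over to the real comparison. In a further simulated set without changed genes, camera put 1.5% of 200 random lists of 25 genes below an unadjusted p of 0.05. All simulated genes were drawn independently of each other. The 1.5% therefore does not test the preset correlation for the real lists, where estimates reached 0.742 (MHC class II presentation).

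Alternatives covered median centring, cyclic loess and centring on reference genes on top of the deposited values, leaving out the dimmest 30% of genes, averaging a gene's rows, trended and robust eBayes, array weights, the replicate number as a block, leaving out each array in turn, other thresholds, testing every row, camera with ranks, and Spearman correlation. A term for the sex-linked split of the arrays was added after seeing the data. Rows without a single symbol were left out of the main test because their gene cannot be named. In a fit of every row, 354 of the 5530 unlisted rows (6.4%) and 175 of the 1621 rows with several symbols (10.8%) passed the same thresholds.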

Results

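The series compared bone marrow cells that express stem cell factor with unselected bone marrow. Stem cell factor, encoded by Kitl, is a cytokine that blood stem cells need, and a green fluorescent protein knocked into its gene marks the cells that make it. The design asks which transcripts set these Scf-GFP+ cells apart from the marrow they live in. RNA from 5000 sorted Scf-GFP+ cells and from 5000 sorted whole bone marrow cells was hybridised to Affymetrix whole-transcript arrays, with 3 arrays for each population and 6 in all. Whole bone marrow is a mixture of maturing blood cells with few stromal cells, so each of its values is an average over many cell types.

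The populations differed far more than the replicates did. Across genes, Pearson correlations between arrays were 0.973 to 0.975 within Scf-GFP+ cells, 0.978 to 0.981 within whole marrow and 0.818 to 0.834 between the groups. Genes are not independent replicates, so these correlations describe the arrays and are not a test. The median standard deviation (SD) of a gene over 3 arrays was 0.165 in Scf-GFP+ cells and 0.162 in whole marrow on the log2 scale. Of 19938 genes, limma called 1796 higher and 1574 lower in Scf-GFP+ cells, together 16.9%, at an adjusted p below 0.05 and at least 2-fold. A difference of at least 8-fold was reached by 373 of the genes called higher and by 368 of those called lower. All arrays of one group lay above all arrays of the other for 3794 genes higher and 5256 genes lower in Scf-GFP+ cells, where chance gives 10% of genes for 3 arrays against 3. The arrays also differed in sex-linked transcripts. Xist, the RNA that silences one X chromosome in female cells, measured 11.50 and 11.81 in Scf-GFP+ replicates 1 and 2 and between 4.99 and 5.10 in Scf-GFP+ replicate 3 and the 3 whole marrow arrays. The Y-linked gene Eif2s3y measured at most 4.41 in the first pair and at least 7.33 in the other 4 arrays. With a term for this split, added after seeing the data, 1579 genes were called higher and 1288 lower. The group difference in that model is Scf-GFP+ replicate 3 alone minus whole marrow, with the spread taken from the other arrays.

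Of the 12 genes fixed in advance, 8 were called higher in Scf-GFP+ cells, 2 lower and 2 neither. Kitl itself was 47.5-fold higher (log2 difference 5.57 ± 0.22 SE, n = 3 arrays per group, limma adjusted p = 1.0e-05). Since the cells were sorted on expression from this gene, its value checks the labels and is not a finding. Cxcl12, a chemokine that retains blood stem cells in the marrow, was higher by 6.09 ± 0.25. Lepr, the leptin receptor, was 90.2-fold higher (6.50 ± 0.17), Pdgfra and Pdgfrb, receptors for platelet-derived growth factor on mesenchymal and perivascular cells, were higher by 4.97 ± 0.11 and 5.25 ± 0.11, and Angpt1, a ligand of the endothelial receptor Tek, by 5.03 ± 0.11. Vcam1, an adhesion molecule, and Alpl, alkaline phosphatase, were higher by 3.49 ± 0.20 and 3.45 ± 0.16. The adjusted p of these 8 genes lay between 2.0e-06 and 4.0e-05, and each was higher in all 3 Scf-GFP+ arrays than in any whole marrow array. Ptprc, which encodes the leukocyte marker CD45, was lower by -3.52 ± 0.74 (adjusted p = 0.0137; -4.45 without Scf-GFP+ replicate 1, adjusted p = 8.43e-05, from 8.43e-05 to 0.0495 over the alternatives), and Pecam1, which endothelial cells and several blood cells express, was lower by -1.90 ± 0.26 (adjusted p = 0.00200). Nes, which encodes nestin, measured 5.13 ± 0.34 (SD, n = 3) in Scf-GFP+ cells and 4.91 ± 0.14 in whole marrow, a difference of 0.22 ± 0.19 SE that did not pass the test (adjusted p = 0.437). Cspg4, which encodes the pericyte proteoglycan NG2, differed by -0.13 ± 0.12 and did not pass either (adjusted p = 0.474). Both group means of Nes lay below the first quartile of every array (5.19 to 5.31), where arrays lose resolution.

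**Figure D1:**
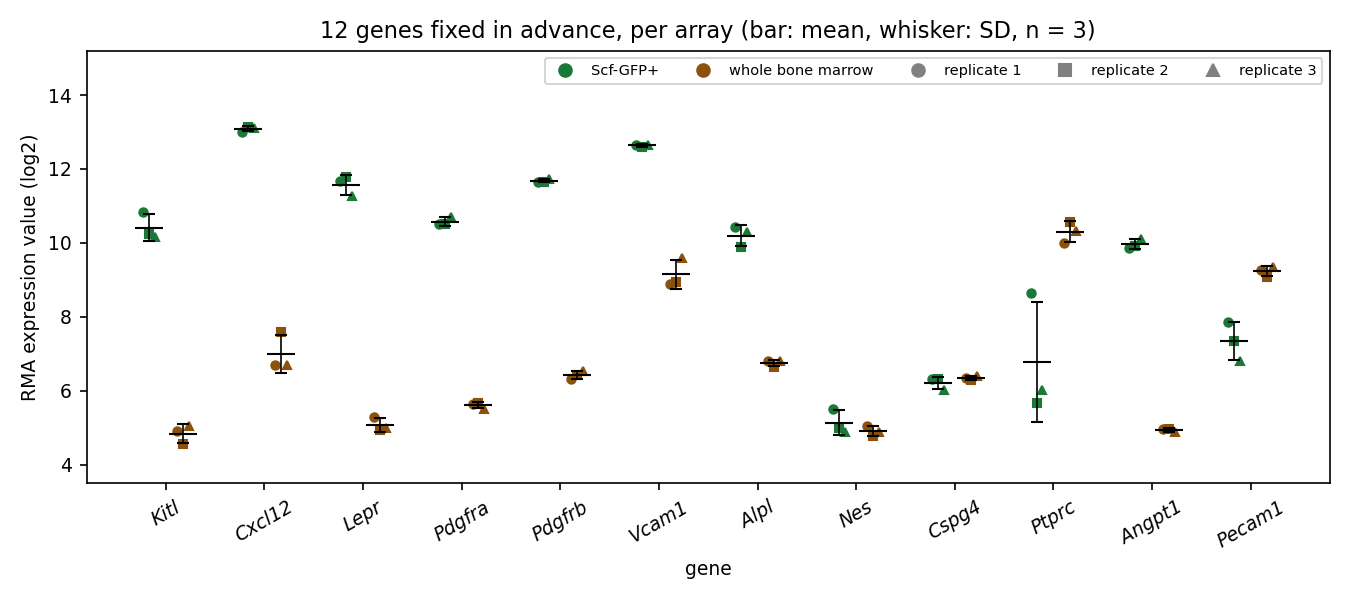
Log2 RMA expression values (vertical axis) of the 12 genes fixed in advance (horizontal axis) on each of the 6 arrays, with green points for Scf-GFP+ cells, brown points for whole bone marrow, symbols for replicate numbers, black bars for means and whiskers for SD (n = 3). Kitl, Cxcl12, Lepr, Pdgfra, Pdgfrb, Vcam1, Alpl and Angpt1 lie higher in every Scf-GFP+ array, Ptprc and Pecam1 lower, and Nes and Cspg4 overlap between the groups.

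With all arrays, the largest differences reached 133-fold for genes higher in Scf-GFP+ cells and 87.4-fold for genes lower in them. Ibsp, bone sialoprotein, led the higher genes (7.05 ± 0.18 SE). It was followed by Akr1c19, an aldo-keto reductase, at 6.95 ± 0.20, Gdpd2 at 6.82 ± 0.12, Kng1, kininogen, at 6.79 ± 0.18, and Adipoq, the adipocyte hormone adiponectin, at 6.78 ± 0.22. Igfbp5, C1s1, Fgf7, Mme, Fmo2, Efemp1, Chrdl1, Lepr, Fap and Esm1 completed the 15 largest, with differences from 6.75 down to 6.45. The values of Gdpd2 in Scf-GFP+ cells, 13.30 to 13.37, lay at the upper end of the arrays' range. Arrays lose resolution at the ends of their range, so the sizes and the order of the largest differences are approximate. Among the genes lower in Scf-GFP+ cells, Prg2, the eosinophil major basic protein, differed by -6.45 ± 0.25, Gch1, the first enzyme of tetrahydrobiopterin synthesis, by -6.44 ± 0.22, and Car1, a red cell carbonic anhydrase, by -6.41 ± 0.25. Cd52, Ifitm6, Vpreb1, Kel, Cldn13, Ly6g, Ccl3, Trem1, Mpo, Cd72, Chil3 and Ctse followed with differences from -6.08 to -5.52. The standard errors of Cd52, Ifitm6 and Ly6g were 0.78, 1.10 and 1.05, because Scf-GFP+ replicate 1 lay above replicates 2 and 3. Ifitm6 measured 8.85, 4.49 and 4.77 in the 3 Scf-GFP+ arrays. Without replicate 1, Ifitm6 differed by -7.42, Ly6g by -7.11 and Cd52 by -7.06, ahead of Prg2 (-6.47), so the order of the genes lower in Scf-GFP+ cells depends on this array.

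Most of the listed niche factors and perivascular markers were called higher in Scf-GFP+ cells. Of 23 measured niche factors, 16 were called higher and 3 lower in Scf-GFP+ cells. Besides the fixed genes, those higher included Fgf7, a fibroblast growth factor, at 6.73 ± 0.15, Bmp4 at 5.57 ± 0.11, the chemokine Cxcl14 at 5.43 ± 0.14, Il7, a cytokine that B cell progenitors need, at 4.24 ± 0.13, Igf1 at 4.23 ± 0.21, and Csf1, which macrophages need, at 3.41 ± 0.25. Il6, Pf4, a platelet chemokine, and Tgfb1 were called lower, at -4.06 ± 0.12, -3.61 ± 0.45 and -1.65. Limma's camera test gave the list an adjusted p of 4.87e-08 (adjusted p = 0.0569 with an estimated correlation). Kitl is a member. Of 30 perivascular stromal markers, 19 were called higher and 1 lower, with a median difference of 2.83 (camera adjusted p = 1.77e-14, and 0.0167 with an estimated correlation). Examples are Fbln5, an elastic fibre protein, at 5.80 ± 0.13, and the transcription factors Ebf3 at 5.40 ± 0.14, Prrx1 at 5.11 ± 0.14 and Foxc1 at 4.43 ± 0.26. The member called lower was Bst1, an ectoenzyme also made by myeloid cells, at -3.19 ± 0.27.

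Transcripts of the bone lineage were high in Scf-GFP+ cells, those of the fat lineage in part, and most of those of cartilage were not called. Of 19 osteoblast lineage genes, 14 were called higher and 1 lower (camera adjusted p = 4.6e-12, and 0.0402 with an estimated correlation). After Ibsp the largest were Phex, a peptidase that regulates phosphate, at 5.76 ± 0.24, Ogn at 5.69 ± 0.18, Cdh11, a mesenchymal cadherin, at 5.66 ± 0.13 and Sparc, osteonectin, at 5.38 ± 0.25. Sp7, a transcription factor of osteoblast commitment, was higher by 3.14 ± 0.17. The member called lower, Ifitm5, differed by -1.41 (adjusted p = 0.0143) and did not pass without whole marrow replicate 1 (adjusted p = 0.0534, from 0.00464 to 0.149 over the alternatives). Of 21 adipocyte lineage genes, 6 were called higher and 1 lower. Those higher included Adipoq, lipoprotein lipase (Lpl) at 5.21 ± 0.23, Pparg, the transcription factor that drives fat cell differentiation, at 3.89 ± 0.25 and its regulator Zfp423 at 3.27 ± 0.22. Plin1, which coats the lipid droplet of mature fat cells, differed by -0.29 ± 0.12 and was not called. The list as a whole did not pass camera (adjusted p = 0.232), and its median of -0.22 and mean of 0.81 had opposite signs. Its 1 lower call, Pnpla2, a triglyceride lipase, became 2 without Scf-GFP+ replicate 1 or without whole marrow replicate 1, and 3 without Scf-GFP+ replicate 3. Of 17 chondrocyte lineage genes 15 were not called, among them Acan at 0.10 ± 0.12 and Sox9 at 0.08 ± 0.11, and the list did not pass (camera adjusted p = 0.844). The mean of this list, 0.02, lay above 0 while its median, -0.10, and the direction of the test lay below. The called members, Comp at 1.62 ± 0.39 (adjusted p = 0.0235) and Sox6 at -1.75 ± 0.39 (adjusted p = 0.0164), each lost the call when single whole marrow arrays were left out. Without whole marrow replicate 1, 2 or 3 the adjusted p of Comp was 0.0590, 0.0716 or 0.0748, and without replicate 3 that of Sox6 was 0.0556. Over all alternatives the range was 0.000416 to 0.0748 for Comp and 0.00298 to 0.118 for Sox6.

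Markers of other cells of the vessel wall and of nerves were mixed. Of 18 smooth muscle and mural cell genes, 8 were called higher, led by Rgs5, a pericyte regulator of G protein signalling, at 3.59 ± 0.39, the potassium channel subunit Abcc9 at 2.76 ± 0.20, Mylk at 2.24 ± 0.19 and Notch3 at 1.92 ± 0.21 (camera adjusted p = 0.00133, and adjusted p = 0.0865 with an estimated correlation). The contractile genes Acta2 (-0.65 ± 0.34) and Myh11 (0.85 ± 0.14) were not called, although Acta2 was called lower without Scf-GFP+ replicate 2 (-1.02, adjusted p = 0.0250, from 0.0250 to 0.438 over the alternatives). Of 24 endothelial genes, 5 were called higher, 2 lower and 17 neither. Ramp2, a subunit of the adrenomedullin receptor, was higher by 4.20 ± 0.18 (18.4-fold), Emcn, endomucin, by 2.20 ± 0.18 and Clec14a by 1.69 ± 0.12, while the vascular growth factor receptors Kdr and Flt4 differed by 0.17 ± 0.22 and 0.20 ± 0.20 and were not called. The list passed camera (adjusted p = 0.0204) but not with an estimated correlation (adjusted p = 0.482), nor without Scf-GFP+ replicate 1 (adjusted p = 0.121, from 0.00292 to 0.544 over the alternatives). The 2 lower calls became 1 without Scf-GFP+ replicate 2 or 3 or without whole marrow replicate 1, 2 or 3, while Pecam1 stayed called throughout. Among the higher calls, Cdh5 at 1.40 (adjusted p = 0.0345) was lost without Scf-GFP+ replicate 1 or 2 (limma adjusted p = 0.0971 and 0.0675). It was also lost without whole marrow replicate 1, 2 or 3 (limma adjusted p = 0.0795, 0.0773 and 0.110). Of 16 genes of Schwann cells and neurons, S100b at 4.28 ± 0.28 and Pmp22 at 3.88 ± 0.38 were called higher. The calcium-binding protein S100b and the membrane protein Pmp22 are also made outside nerves, and Sox10, the transcription factor of Schwann cells, differed by -0.13 ± 0.12. That list did not pass camera (adjusted p = 0.622), and its median of -0.13 and mean of 0.32 had opposite signs.

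All lists of extracellular matrix genes had more members called higher than lower in Scf-GFP+ cells. Of 31 matrix remodelling enzymes and their inhibitors, 24 were called higher and 1 lower (camera adjusted p = 2.5e-15, and 0.0167 with an estimated correlation). The collagenase Mmp13 was higher by 5.89 ± 0.19, Serping1, a protease inhibitor, by 5.65 ± 0.17, the crosslinking enzyme Lox by 5.16 ± 0.24 and Pcolce, which promotes procollagen cleavage, by 5.02 ± 0.16. Mmp9, a gelatinase made by neutrophils, was lower by -4.15 ± 0.46. Of 31 basement membrane components and matrix glycoproteins, 21 were called higher, among them Efemp1 at 6.61 ± 0.18 and tenascin C (Tnc) at 6.24 ± 0.16, and 2 were called lower, fibronectin (Fn1) at -2.91 ± 0.13 and Thbs1 at -1.79 ± 0.20. That list passed camera with both correlations (adjusted p = 1.49e-14, and 0.0321 with an estimated one). Of 12 small leucine-rich proteoglycans, 8 were called higher, led by Dcn at 6.05 ± 0.17, Bgn at 5.86 ± 0.16, Lum at 5.47 ± 0.25 and Prelp at 5.12 ± 0.20 (camera adjusted p = 4.87e-08, and adjusted p = 0.0589 with an estimated correlation). Of 24 collagens, 8 were called higher, among them Col8a1 at 4.44 ± 0.23, Col6a1 at 3.73 ± 0.12 and Col1a2 at 2.12 ± 0.10. Col1a1, which encodes the other chain of type I collagen, differed by 0.28 ± 0.10 and was not called. The collagens passed camera (adjusted p = 1.23e-06) but not with an estimated correlation (adjusted p = 0.0586).

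All lists of growth factor pathways had more members called higher than lower in Scf-GFP+ cells. Of 37 genes of BMP and TGF-beta signalling, 19 were called higher and 2 lower (camera adjusted p = 5.71e-09, and 0.0336 with an estimated correlation). These included both ligands and extracellular antagonists, with Bmp5 at 6.08 ± 0.13, Bmp6 at 4.60 ± 0.15, the BMP antagonist Chrdl1 at 6.52 ± 0.13 and Fstl1 at 6.17 ± 0.11. The genes called lower were Tgfb1 and the BMP target Id2. Id2, at -1.90 (adjusted p = 0.0286), lost the call without Scf-GFP+ replicate 1 or 2 or whole marrow replicate 1 or 3, with adjusted p values of 0.0871, 0.0826, 0.0845 and 0.0971 (from 0.00185 to 0.204 over the alternatives), which left 1 gene called lower in each case. Of 15 genes of the insulin-like growth factor axis, 9 were called higher, led by the binding proteins Igfbp5 at 6.75 ± 0.10 and Igfbp7 at 5.10 ± 0.15, the protease Pappa at 4.81 ± 0.34 and the signalling adaptor Irs1 at 4.70 ± 0.15 (camera adjusted p = 1.15e-06, and 0.0456 with an estimated correlation). Of 36 genes of Wnt signalling, 15 were called higher. Sfrp4 at 6.33 ± 0.36 and Sfrp1 at 4.54 ± 0.26, which bind Wnt ligands, stood beside Rspo3, which amplifies the signal, at 4.48 ± 0.14 and the transcription factor Tcf7l2 at 3.49 ± 0.12. This list passed camera (adjusted p = 5.03e-07) but not with an estimated correlation (adjusted p = 0.0586). Of 19 genes of Notch signalling, 6 were called higher, among them Hes1 at 2.48 ± 0.46, Hey1 at 2.21 ± 0.17 and the ligand Jag1 at 1.84 ± 0.18 (camera adjusted p = 0.0151, and adjusted p = 0.171 with an estimated correlation). It did not pass without the dimmest 30% of genes (adjusted p = 0.0533, from 0.00602 to 0.171 over the alternatives).

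Transcripts of blood lineages were lower in Scf-GFP+ cells in nearly every list, by a margin that differed between arrays for neutrophil genes. Of 26 pan-haematopoietic genes, 25 were called lower, among them Btk at -4.29 ± 0.19, Vav1 at -3.75 ± 0.19, Ikzf1 at -3.68 ± 0.15 and the myeloid and B cell transcription factor Spi1 at -3.90 ± 0.28 (camera adjusted p = 3.97e-15, and adjusted p = 0.131 with an estimated correlation). All 24 erythroid genes were called lower, including the membrane proteins Kel at -5.82 ± 0.25, Rhag at -5.40 ± 0.33 and Slc4a1 at -5.18 ± 0.14 (camera adjusted p = 2.36e-19, and adjusted p = 0.0586 with an estimated correlation). Of 25 B cell genes, 22 were called lower, with Cd72 at -5.60 ± 0.19 and Cd79b at -4.59 ± 0.11, and 1 was called higher, the transcription factor Ebf1 at 2.18 ± 0.19, which is also a perivascular marker here (camera adjusted p = 6.76e-13, and adjusted p = 0.0976 with an estimated correlation). Of 23 genes of T and NK cells, 9 were called lower, led by Cd3d at -5.24 ± 0.17 and Cd2 at -4.37 ± 0.10 (camera adjusted p = 3.92e-06, and adjusted p = 0.0586 with an estimated correlation). Of 13 genes of eosinophils, basophils and mast cells, 7 were called lower, and 8 adjusted over the list alone, with Prg2 and the basophil protease Mcpt8 (-5.13 ± 0.23) in front (camera adjusted p = 3.36e-06, and 0.0402 with an estimated correlation). Of 17 genes of megakaryocytes and platelets, 4 were called lower, Nfe2 at -4.66 ± 0.23, Pf4, Plek at -2.93 ± 0.22 and Thbs1, of which Nfe2 and Plek also serve other blood cells (camera adjusted p = 0.000147, and adjusted p = 0.0586 with an estimated correlation).

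Of 30 neutrophil lineage genes, 27 were called lower, and 29 adjusted over the list alone (camera adjusted p = 1.77e-14, and adjusted p = 0.131 with an estimated correlation). The granule enzymes Mpo (-5.61 ± 0.14), Ctsg (-5.03 ± 0.15) and Elane (-4.14 ± 0.14) had small errors. Genes of later maturation did not, because Scf-GFP+ replicate 1 stood apart. S100a8, an abundant calcium-binding protein of neutrophils, measured 12.44 in Scf-GFP+ replicate 1, 6.01 and 6.49 in replicates 2 and 3, and on average 13.03 in whole marrow. S100a8 (-4.71 ± 1.61, adjusted p = 0.0770) and S100a9 (-3.54 ± 1.17, adjusted p = 0.0690) were not called with all arrays as deposited. Over the alternatives their adjusted p ranged from 1.82e-05 to 0.191 and from 1.82e-05 to 0.176. Centring on reference genes led to a call of both (0.0336 and 0.0297), as did leaving out the dimmest genes for S100a9 (0.0493). Without Scf-GFP+ replicate 1, S100a8 differed by -6.78 and S100a9 by -5.03, both were called, and 29 of the 30 genes were called lower. Without Scf-GFP+ replicate 2 or 3 or whole marrow replicate 1 the count was 23, and without whole marrow replicate 2 or 3 it was 22. Against the whole marrow mean, the median over the list was -2.99 in replicate 1, -5.02 in replicate 2 and -4.98 in replicate 3. For pan-haematopoietic genes these medians were -2.86, -3.96 and -3.97, and for erythroid genes -4.19, -3.91 and -4.10. Without Scf-GFP+ replicate 1, limma called 1698 genes higher and 1498 lower in total.

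**Figure D2:**
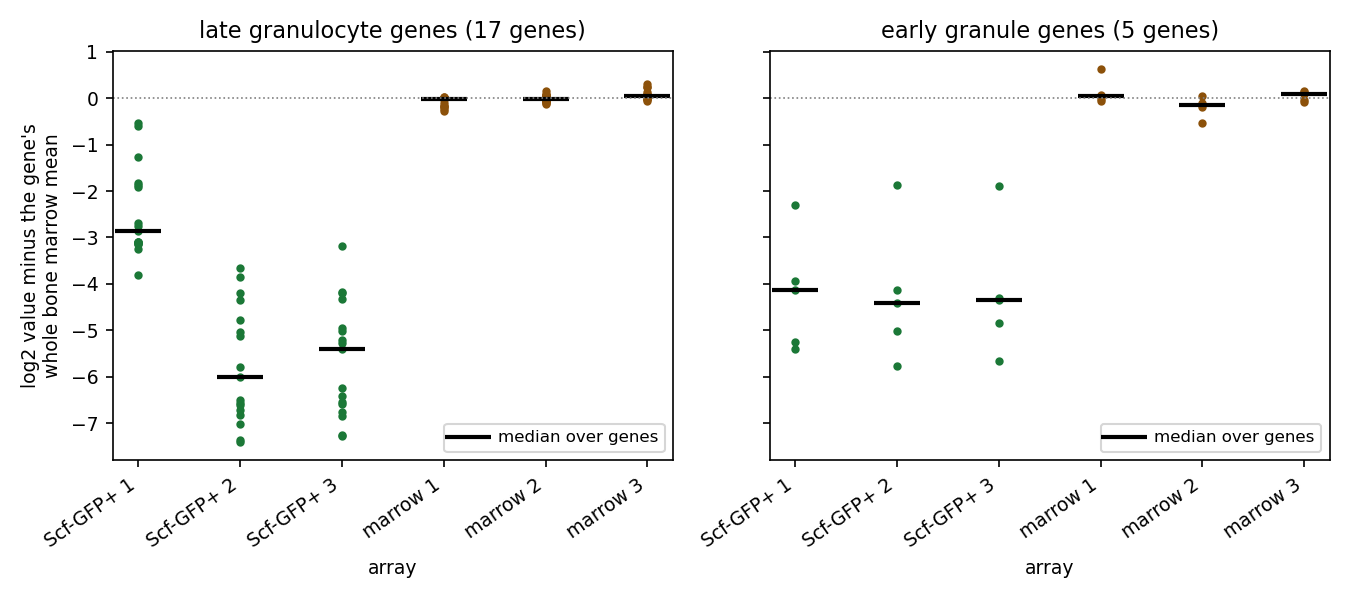
Log2 value of each gene minus its whole bone marrow mean (vertical axis) on each of the 6 arrays (horizontal axis), for 17 late granulocyte genes and 5 early granule genes, with 1 point per gene and a black bar for the median over genes. Late genes lie closer to whole marrow in Scf-GFP+ replicate 1 than in replicates 2 and 3, while early genes lie at similar distances in the 3 Scf-GFP+ arrays.

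The lists of macrophage and of stem and progenitor genes were mixed, while most antigen presentation genes were called lower. Of 23 genes of monocytes, macrophages and osteoclasts, 8 were called lower, such as F13a1 at -3.55 ± 0.16, Acp5 at -3.14 ± 0.17 and Csf1r at -2.09 ± 0.25, and 2 were called higher. Those were Ctsk, a collagen-degrading protease of osteoclasts and fibroblasts, at 5.27 ± 0.20, and Vcam1 (camera adjusted p = 0.00144, and adjusted p = 0.0586 with an estimated correlation). Of 19 genes of haematopoietic stem and progenitor cells, 8 were called lower, led by Cd48 at -4.10 ± 0.18 and Myb at -3.26 ± 0.13, and 2 were called higher, Runx1 at 2.16 ± 0.17 and Hoxa9 at 1.55 ± 0.13. Kit, the receptor for stem cell factor, differed by -0.26 ± 0.19 and was not called. The list did not pass camera (adjusted p = 0.0531, and 0.133 with an estimated correlation), but did without Scf-GFP+ replicate 1 (0.0315) or without whole marrow replicate 3 (0.0395), with a range of 0.0134 to 0.133 over the alternatives. Of 9 genes of MHC class II presentation, 8 were called lower, with H2-Aa at -4.97 ± 0.33 and H2-Ab1 at -4.41 ± 0.23 (camera adjusted p = 3.87e-06, and adjusted p = 0.171 with an estimated correlation).

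Scf-GFP+ cells had lower levels of cell cycle transcripts than whole marrow. Of 39 proliferation genes, 38 were called lower, with a median difference of -3.24 (camera adjusted p = 4.87e-26, and 0.0321 with an estimated correlation). E2f8 at -5.09 ± 0.25, topoisomerase 2-alpha (Top2a) at -5.03 ± 0.23, Birc5 at -4.59 ± 0.10 and Mki67, which encodes the Ki-67 antigen, at -4.28 ± 0.36 are examples. Immediate early genes and genes known to respond to tissue dissociation were lower as well, with 20 of 29 called lower and 3 higher (camera adjusted p = 9.86e-08, and adjusted p = 0.0586 with an estimated correlation). The heat shock gene Hspa1a differed by -5.07 ± 0.38 and the transcription factors Nr4a1, Atf3 and Fos by -4.82 ± 0.21, -4.08 ± 0.17 and -1.93 ± 0.23. Higher were Ccn1 at 2.71 ± 0.56, Ccn2 at 2.36 ± 0.44, secreted proteins that mesenchymal cells also make, and Socs3 at 1.93 ± 0.23. For comparison, 21 reference genes had a median difference of -0.15, with 1 called higher and 2 lower. These were Emc7 at 1.27, Pgk1 at -1.15 and Tfrc, the transferrin receptor that erythroid precursors carry in quantity, at -5.16.

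**Figure D3:**
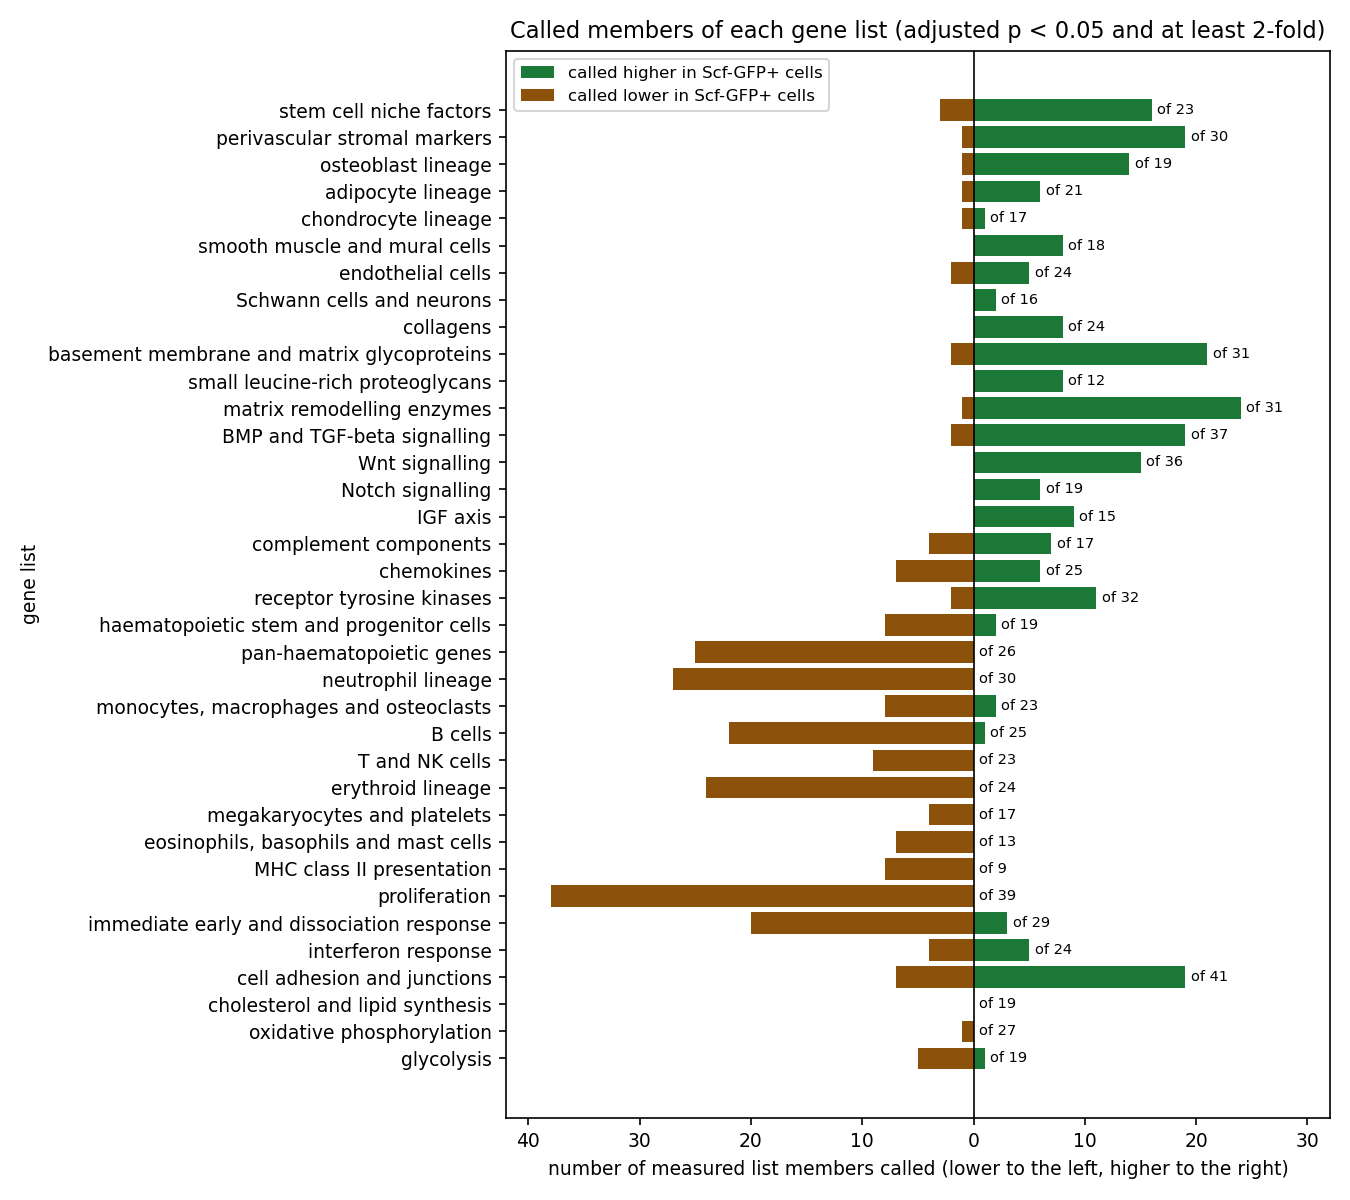
Number of measured members called higher (green, to the right) or lower (brown, to the left) in Scf-GFP+ cells for each of the 36 tested gene lists (vertical axis), with the number measured beside each bar. Matrix, stromal and growth factor lists extend to the right, and blood lineage and proliferation lists to the left, up to 38 of 39 proliferation genes.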

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

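No alternative turned a call into the opposite one, and the 12 genes fixed in advance stayed on their side of the threshold wherever they were tested. They were not refitted under the other thresholds or in the fit of every row, and Nes is not among the genes left without the dimmest 30%. The counts depend mostly on the threshold. With no fold minimum 2758 genes were higher and 2635 lower, and limma's test against a 2-fold difference left 792 and 792. Leaving out single arrays gave 1618 to 1822 higher, 1448 to 1560 lower and 27 to 30 gene lists. Other normalizations gave 1615 to 1894 higher and 1501 to 1846 lower, and moved the median over all genes from -0.08 to 0.01 (cyclic loess) or -0.21 (centring on reference genes). Of the genes reported as higher and lower, 1598 and 1574 were also called after that centring. The sex term, added after seeing the data, kept 1353 and 1187 of them, and the cause of the loss was not tested. It turned Tubb3, which was not called at -0.03, into a call at 1.74, because the group difference is then Scf-GFP+ replicate 3 alone, where Tubb3 was at least 2.63 above replicates 1 and 2. Of 28 gene lists past the threshold, 8 passed with an estimated correlation. Lists among them with an estimate below the preset 0.01 also had a higher camera adjusted p. For matrix remodelling enzymes (-0.0224) it rose from 2.5e-15 to 0.0167. For monocytes, macrophages and osteoclasts (-0.0133) it rose from 0.00144 to 0.0586. This argues against a larger correlation between genes as the cause in these lists, and other causes were not tested. The highest correlation between groups fell from 0.834 to 0.637 without the dimmest genes; the cause was not tested. With the replicate number as a block (replicate block), 1775 genes were higher and 1563 lower. Same-numbered arrays deviated from their group means with correlations of -0.063, -0.022 and 0.066, and not every array correlated best with its own number, so the numbers were not taken as pairs. The endothelial list passed or missed the threshold between adjusted p values of 0.00292 and 0.544 over the alternatives, and the interferon list between 0.0254 and 0.196. RMA values give no signal over background, so low genes could not be judged for detection.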

Other observations

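Transcripts of chemokines, complement components, receptors and adhesion molecules went both ways between Scf-GFP+ cells and whole marrow. Of 25 chemokines, 6 were called higher and 7 lower, and the list as a whole did not pass camera (adjusted p = 0.519), with a median of -0.02 and a mean of 0.16. Ccl19, a ligand for lymphocytes and dendritic cells, was higher by 4.72 ± 0.18 (SE, n = 3 arrays per group) and Cxcl9 by 4.53 ± 0.34, while Ccl3 was lower by -5.71 ± 0.25 and Cxcl2, which attracts neutrophils, by -3.35 ± 0.35. Of 17 complement components, 7 were called higher and 4 lower, and the list did not pass camera with all arrays (adjusted p = 0.0870, and 0.0494 without Scf-GFP+ replicate 3, from 0.0196 to 0.691 over the alternatives; median -0.08, mean 1.30). Early components and a regulator were higher, C1s1 by 6.73 ± 0.18, C4b by 5.25 ± 0.18, Cfb by 4.81 ± 0.21 and Serping1 by 5.65 ± 0.17, and the receptor C5ar1 was lower by -3.33 ± 0.34. Of 32 receptor tyrosine kinases, 11 were called higher, such as Fgfr2 at 4.99 ± 0.14 and Egfr at 3.99 ± 0.16, and 2 lower, the blood cell receptors Csf1r and Flt3 (camera adjusted p = 3.92e-06, and adjusted p = 0.0617 with an estimated correlation). Of 41 adhesion and junction genes, 19 were called higher, 20 adjusted over the list alone, and 7 lower. N-cadherin (Cdh2) at 4.76 ± 0.15 and connexin 43 (Gja1) at 4.51 ± 0.22 were higher and the leukocyte integrins Itga4 and Itgb2 were lower, at -3.91 ± 0.33 and -3.51 ± 0.38 (camera adjusted p = 4.74e-05, and adjusted p = 0.0586 with an estimated correlation). Some further genes were chosen after their values were seen, so they stand for themselves and for no group. Osm, the cytokine oncostatin M, was lower by -4.92 ± 0.44, and its receptor chains Osmr and Lifr were higher by 5.13 ± 0.21 and 5.50 ± 0.48. Cxcr4, the receptor for Cxcl12, was lower by -4.23 ± 0.22. Chosen in the same way, the enzyme genes Aldh1a2, Cyp1b1, Fmo1 and Adh1 were higher, at 6.01 ± 0.37, 5.78 ± 0.13, 5.88 ± 0.35 and 5.28 ± 0.24, and the inflammatory genes Il1b and Ptgs2 were lower by -5.44 ± 0.43 and -4.73 ± 0.26.

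Of 27 genes of oxidative phosphorylation, 1 was called lower, and 0 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.889). The called member, Cox5a at -1.02 (adjusted p = 0.0121), fell short of 2-fold without Scf-GFP+ replicate 1 (-0.80) or whole marrow replicate 3 (-0.96), which left no member called, with 5 lower and 2 higher at an unadjusted p below 0.05 in the limma fit of all arrays. None of 19 genes of cholesterol and lipid synthesis was called by limma, while 6 were lower and 1 higher at an unadjusted p below 0.05. Camera gave that list an adjusted p of 0.0822, and 0.0300 without Scf-GFP+ replicate 3, when 2 genes were called lower, with a range of 0.0300 to 0.349 over the alternatives. Of 19 glycolysis genes, 5 were called lower, 6 adjusted over the list alone, and 1 higher (camera adjusted p = 0.00486, and adjusted p = 0.0976 with an estimated correlation). The lactate transporter Slc16a3 at -3.34 ± 0.20 and the hexokinases Hk3 and Hk2 at -2.26 ± 0.19 and -1.64 ± 0.15 were lower, and Ldhb, a lactate dehydrogenase subunit, was higher by 1.83 ± 0.14. Interferon response genes went both ways, with 5 of 24 called higher, 6 adjusted over the list alone, and 4 lower. Iigp1 at 5.17 ± 0.22 and Ifit3 at 1.57 ± 0.19 were higher, and Rsad2 at -2.51 ± 0.42 and Mx1 at -1.41 ± 0.17 lower. This list passed camera at an adjusted p of 0.0365, but not with an estimated correlation (adjusted p = 0.196), nor without Scf-GFP+ replicate 1 (0.0598), Scf-GFP+ replicate 2 (0.0734) or whole marrow replicate 1 (0.0745), with a range of 0.0254 to 0.196 over the alternatives.

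All tests below were chosen after the results they bear on were seen, except the count of gene lists over other splits. Neutrophil transcripts stood out in Scf-GFP+ replicate 1. Over 17 late granulocyte genes that array exceeded the mean of replicates 2 and 3 by a median of 3.47 (quartiles 1.64 and 4.49), while 5 early granule genes exceeded it by at most 0.31. A carry-over of whole marrow RNA or cells is argued against by the erythroid list, whose median excess was -0.0641 with an upper quartile of 0.11, and a mislabelled marrow array by the 30 perivascular markers, which differed by a median of 0.0490 (quartiles -0.118 and 0.211). What remains is that granulocytes of later stages, or their RNA, may have entered this sample, although double sorting for GFP would be expected to remove them. The late genes were not split further, so mature neutrophils were not told apart from their precursors. Whether the excess arose in the animal or during preparation stays open. Of 33 genes that were over 2 log2 units above both other Scf-GFP+ arrays there, with those arrays within 1 of each other, 32 were also higher in whole marrow than in replicates 2 and 3.

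Xist and Y-linked transcripts split the arrays. The gap in Xist between Scf-GFP+ replicates 1 and 2 and the other 4 arrays was 6.40, and Eif2s3y and Kdm5d lay on the opposite side in every array, so the Scf-GFP+ cells may come from animals of both sexes and the marrow cells from males. A limma model with terms for the group and for this split called 2867 of all genes for the group and 14 for the split. Its group difference is 1 array, Scf-GFP+ replicate 3, against whole marrow, with the spread taken from the other arrays. The term for the split sets Scf-GFP+ replicates 1 and 2 against that same array, so few calls for it do not show a small effect. The part of sex in the calls therefore stays open. Replicate 3 also differed from replicates 1 and 2 in Prg4, at 8.54 against 4.93 and 4.72, and in Tubb3, at 8.67 against 6.04 and 5.98.

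Of 29 immediate early genes 20 were called lower and 3 higher in Scf-GFP+ cells, and the list passed camera with the preset correlation only (adjusted p = 0.0586 with an estimated correlation). An offset from the normalization is argued against, because the reference genes had a median difference of -0.151 and the upper quartile of the immediate early list lay below it, at -0.432. Whether the cells differed in the animal, or whether sorting and handling acted differently on them, cannot be told apart, since each population was prepared in its own way (upper quartile -0.432 in either case). A low level of these genes in the double-sorted cells may be worth following up with both populations handled alike.

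A hypothesis was that the endothelial transcripts in Scf-GFP+ cells came from a variable share of endothelial cells in the sort. Cdh5 and Emcn were highest in replicate 2 and lowest in replicate 3, so other endothelial genes should follow that order. Of 22 others, 5 did (22.7%), more than in 78.8% of 10000 random lists matched on expression and short of the 95% set for the test. The test could not decide, because the share did not lie below the median of random lists (13.6%) either. It asked for 1 exact order, taken from Cdh5 and Emcn alone. The list as a whole varied in another order, with medians above whole marrow of 0.45, 0.28 and 0.06 in replicates 1, 2 and 3. The correlation that camera estimated between its genes was 0.363. Endothelial cells may also be part of the population that makes stem cell factor, which was not tested (22.7% bears on the variable share only).

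With 3 arrays against 3 there are 10 splits, too few for a share below 0.05. In each result 1 of the 10 splits, the real one, gave as many calls. The real split gave 1796 genes higher and 1574 lower by limma, and the highest of the other splits gave 0 by limma with 572 genes at an unadjusted p below 0.05. For gene lists by camera with the preset correlation, the real split gave 28 and the highest other split 20. Each of the other splits has arrays of both populations on both sides, in unequal numbers, which widens the spread within the sides. It also leaves part of the real difference between the sides. The counts of the other splits therefore do not measure what chance alone would give.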
